A study of Homo sapiens with 19 samples.

How the data were processed

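Total RNA of 19 orthotopic LNCaP xenograft tumours was poly-A selected, fragmented and turned into cDNA from random primers, per the labels' protocols. The protocols describe both a directional and a non-directional second strand, so which was used is not settled by the labels. Reads were processed with fastp and aligned with HISAT2 2.0.5, per the submitters' processing notes. The counting tool, its settings, and the genome build and annotation are not given in the sources used here. The gene identifiers and coordinates of all 58735 genes were equal to those of GENCODE 29, so coordinates are on GRCh38.

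The authors deposited 1 table of read counts per gene and 1 table of FPKM, both of which hold all 19 libraries. The deposited counts are whole numbers that sum to 21903084 to 60335679 per library, with no entries for unassigned reads. The deposited FPKM equal the count divided by gene length and by the library total, times 1 factor per library that ranges from 0.893 to 1.503 (largest relative deviation within a library 5.2e-15). That factor is the authors' own scaling between libraries, whose method is not given in the sources used here. Chromosome, strand, length and biotype of each gene come from the deposited tables.

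Groups and replicate numbers were taken from the sample titles: control (7), propranolol (6) and combination (6). The labels call these tumours of treated mice, and 1 library per tumour and 1 tumour per mouse were assumed. Counts of libraries within a group differed by far more than sampling noise (chi-square per degree of freedom at least 11.22 for every pair), so no library was counted as a copy of another. The replicate numbers were taken only to number the animals of a group.

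Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM factors, 1 model with a mean per group over all 19 libraries, robust quasi-likelihood F tests, and Benjamini-Hochberg adjustment over the 17418 genes tested, called at 0.05. The contrasts were propranolol against control, combination against control, combination against propranolol, and the mean of both treatments against control. Standard errors of log2 fold changes are the fold change divided by the square root of F. CPM values are scaled by the TMM factors. Fixed gene lists (32, with 776 entries, 3 found by an older or newer symbol and 2 not found) were tested on voom values with limma 3.58.1: camera with a preset correlation of 0.01, adjusted over the 30 lists with at least 5 tested genes, beside camera with an estimated correlation and fry. Camera compares a list with all other genes; fry asks whether a list's genes move one way on balance. Library measures were compared with exact permutation tests on the absolute difference of means.

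Genes are named by a rule set before the data were examined: a fixed panel with KLK3, FKBP5, ADRB1, ADRB3, MKI67, CHGA and ENO2 always; per comparison the 6 protein-coding genes of smallest p in each direction among those called, or the 4 of smallest p where none was called; and up to 3 called members of each list. Some genes of the panel and of the lists, and 2 of the lists, are not reported here. Other list members quoted as examples were chosen after their values were seen. Pseudogenes and non-coding genes are summarised as counts, except where 5 or fewer genes passed.

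The tests, the lists and most alternatives were fixed before the data were examined. Alternatives were DESeq2 1.42.0, limma-voom with sample quality weights, RLE factors, library totals, other filters on low counts, protein-coding genes alone, only the groups compared, the replicate number as a block, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), a covariate from 43 stromal marker genes, other thresholds, and leaving out each library. Chosen after the data had been examined were leaving out propranolol 2 and combination 4, leaving out propranolol 5 as well, and removing each library's trend of log2 CPM on gene length and transcript GC content (splines with 5 degrees of freedom each), alone and with the 2 libraries left out. Transcript sequence of GENCODE 29 was available for 99.9% of tested genes and gave GC content and the share of each gene's 25-mers found in more than 10 genes.

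The steps were tested on simulated counts with 200 changed genes at the real depths, with 1 estimated spread per gene shared by all libraries. The larger spread of propranolol 2 and combination 4 was not placed in those libraries. The rates with 19 libraries therefore hold for an even spread, which the data do not have. With 19 libraries, a 2-fold change was recovered in 39.4% of cases for propranolol against control (17163 genes), 46.2% for combination against control (17170 genes) and 39.1% for combination against propranolol (17172 genes), and a 4-fold change in 81.8%, 70.8% and 79.4%. With 17 libraries a 2-fold change was recovered in 80% (17567 genes), 67.7% (17529 genes) and 66.7% (17540 genes). Of the genes called in the simulations with 19 or 17 libraries, 0% to 6.3% had not been changed. A list of genes shifted by 0.4 on the log2 scale was called in every simulation, and none of 10 unshifted lists was. The simulated genes were drawn independently of each other. The simulation therefore does not test list calls among correlated genes, such as the ribosomal list (estimated correlation 0.571 for propranolol against control). Doses, times and the animals' hormone status were not analysed here.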

Results

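Poly-A RNA was sequenced from 19 tumours that LNCaP cells, an androgen-sensitive human prostate cancer line, had formed in the prostates of mice. The mice had received vehicle (control, n = 7), propranolol (n = 6), or propranolol together with SR59230A (combination, n = 6). Propranolol is a non-selective blocker of beta-adrenergic receptors, and SR59230A is used as a blocker of the subtype encoded by ADRB3. The title of the series places the work in the response of prostate cancer to androgen deprivation. The labels used here give no dose, no time of treatment and no hormone status of the animals. The deposited gene counts summed to 23300817 to 40678240 per control library, 23876057 to 60335679 per propranolol library and 21903084 to 30486272 per combination library.

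Of the 19 libraries, 17 held counts for 23246 to 27099 genes. Propranolol 2 held counts for 15334 genes and combination 4 for 13854, at totals of 23876057 and 21903084. These libraries also had few genes at 1 to 10 counts, 533 and 385, against 6436 to 9706 in the other 17. Mitochondrially encoded transcripts took 4.6% of the counts in propranolol 2 and 6.16% in combination 4, against a mean of 1.13% ± 0.44 (SD, n = 7) in controls. The first principal component of the 500 most variable genes held 86.5% of their variance and set these libraries apart from the rest, and 28.2% without them. Both were kept in the tests, and the number of genes called in each comparison is also given without them (17 libraries), an alternative chosen after the data had been examined.

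Transcript length also ran with the groups. The slope of the difference in log2 CPM from controls on log2 gene length averaged -0.215 in propranolol libraries and -0.167 in combination libraries. Each control was set against the mean of the other controls, so the control average close to 0 is fixed by construction. The controls ranged from -0.16 (control 5) to 0.129. The exact permutation test gave p = 0.0146 for propranolol and p = 0.0111 for combination against control (adjusted p = 0.0559 for both over 24 tests of library measures). The slopes were not recomputed for each relabelling, so these p-values are approximate. Among protein-coding genes, the median log2 fold change of propranolol against control was 0.23 in the shortest 25% of genes (up to 3246 bases) and -0.24 in the longest 25% (from 7507 bases). For combination against control these medians were 0.15 and -0.20. Fold changes of protein-coding genes also followed transcript GC content, with a rank correlation of 0.352 for propranolol and 0.191 for combination against control. For combination against propranolol it was -0.354, beside 0.177 for gene length. These gradients are across genes, which are not independent replicates.

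**Figure D1:**
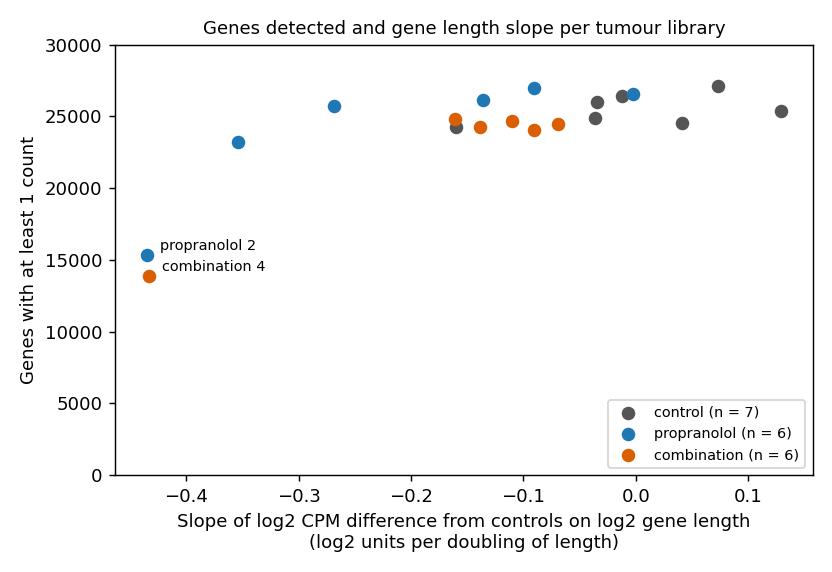
Each point is 1 tumour library; the horizontal axis gives the slope of its log2 CPM difference from controls on log2 gene length, and the vertical axis the number of genes with at least 1 count. Propranolol 2 (15334 genes) and combination 4 (13854 genes) lie below the other 17 libraries, which hold 23246 to 27099 genes.

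The first comparison asked which tumour transcripts differed under propranolol alone. VHL, which encodes the substrate-recognition subunit of the ubiquitin ligase that marks hypoxia-inducible factor alpha subunits for degradation, fell from 171 ± 13.8 CPM in controls (SD, n = 7) to 75.9 ± 27.6 CPM under propranolol (n = 6). XIAP, an inhibitor of caspases, fell from 103 ± 5.09 to 68.1 ± 8.04 CPM, and POMK, a kinase that acts on O-mannosyl glycans of dystroglycan, fell from 8.93 ± 2.20 to 1.96 ± 0.77 CPM. EIF5B, a translation initiation factor that acts in the joining of ribosomal subunits, rose from 89.3 ± 14.9 to 193 ± 42 CPM. ENDOG, a mitochondrial endonuclease, rose from 44.6 ± 5.34 to 87.8 ± 28.9 CPM. For these 5 genes all 6 propranolol libraries lay outside the range of the 7 controls.

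In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 20 of 17418 genes passed, of which 6 were higher and 14 lower under propranolol. The log2 fold change was -2.20 ± 0.26 (SE) for POMK (adjusted p = 0.00122), -1.17 ± 0.19 for VHL (adjusted p = 0.00999) and 1.11 ± 0.17 for EIF5B (adjusted p = 0.00999). The other protein-coding genes with the smallest p that fell were B3GNT10 (-1.29 ± 0.19), RNASEH1 (-0.87 ± 0.14), XIAP (-0.60 ± 0.10) and the zinc finger gene ZNF573 (-1.51 ± 0.25). RNASEH1 encodes a nuclease that removes RNA from RNA-DNA hybrids. Besides EIF5B, the protein-coding genes that rose were ENDOG (0.98 ± 0.17, adjusted p = 0.0157) and BRI3 (0.75 ± 0.14, adjusted p = 0.0292). The BRI3 call was lost without any 1 of control 1, 2, 4, 6 or 7 or propranolol 3 or 5 (adjusted p = 0.067 to 0.117), and the ENDOG call without control 4 (0.0543), control 7 (0.0511) or propranolol 3 (0.0707). With library totals VHL, RNASEH1, ENDOG and BRI3 (0.0676 each) and XIAP (0.0771) did not pass. With only the 2 groups compared VHL (0.0568) and ENDOG (0.0586) did not pass. Without the low count filter XIAP and ZNF573 (0.0559 each) did not. Of the 20 genes, 15 are annotated as protein-coding and 5 carry another biotype, 2 of them pseudogenes. On GRCh38, VHL (ENSG00000134086) spans 10141008 to 10152220 on the plus strand of chromosome 3, and POMK (ENSG00000185900) 43093506 to 43123434 on the plus strand of chromosome 8. EIF5B (ENSG00000158417) spans 99337353 to 99401326 on the plus strand of chromosome 2, and XIAP (ENSG00000101966) 123859724 to 123913979 on the plus strand of chromosome X. EIF5B, ENDOG, BRI3, B3GNT10, XIAP, RNASEH1 and ZNF573 each overlap another annotated gene on the opposite strand. Because the use of strand in counting is not given in the sources used here, reads of the overlapping partners could not be told apart. With each library's trend on gene length and GC content removed, 4 of the 20 genes still passed, among them POMK, VHL and RNASEH1. Of the named genes that did not, XIAP moved to -0.26 (adjusted p = 0.291) and ENDOG to 0.47 (0.244), while EIF5B was at 1.51 (0.171), BRI3 at 1.02 (0.244), B3GNT10 at -1.17 (0.244) and ZNF573 at -1.23 (0.171). All 20 passed when propranolol 2 and combination 4 were left out as well. Of the transcript 25-mers of VHL 6.8% occur in more than 10 genes, of XIAP 8% and of BRI3 8.3%. The share was 5.3% for POMK, 4.8% for RNASEH1 and 2.5% for ZNF573, and 0% for EIF5B, ENDOG and B3GNT10.

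**Figure D2:**
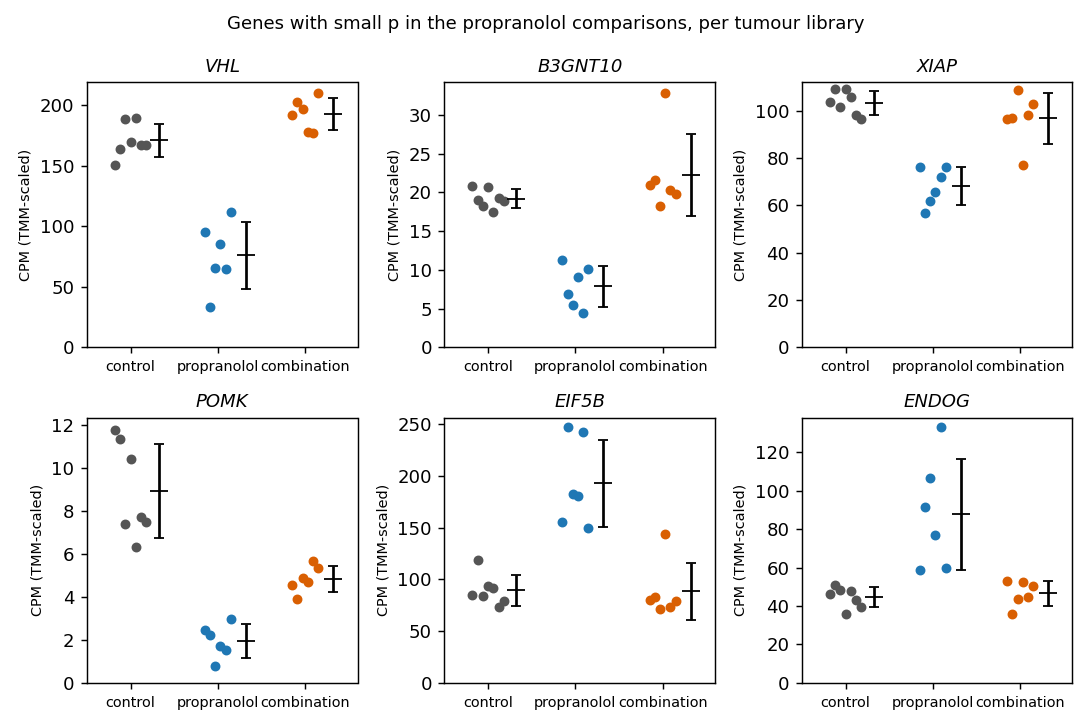
Each point is the TMM-scaled CPM of 1 tumour library for 6 genes named in the propranolol comparison, by group (control n = 7, propranolol n = 6, combination n = 6), and the black marks give the mean and SD. VHL, B3GNT10, XIAP and POMK lie lower in all 6 propranolol libraries than in all 7 controls, and EIF5B and ENDOG higher.

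KLK3, FKBP5 and ADRB1 did not pass under propranolol. KLK3, which encodes prostate-specific antigen, had 5338 ± 374 CPM in controls and 6095 ± 1063 CPM under propranolol (log2 fold change 0.19 ± 0.14, edgeR adjusted p = 0.405). FKBP5, a gene induced by androgen, had 116.4 ± 35.3 and 84.7 ± 44.2 CPM (adjusted p = 0.293). ADRB1, which encodes a beta-adrenergic receptor, had 2.39 ± 1.10 and 4.09 ± 3.94 CPM (adjusted p = 0.426). Its propranolol mean leans on propranolol 3 (11.7 CPM), with the other propranolol libraries at 1.09 to 4.72 CPM. ADRB3 had 0 counts in all 19 libraries, which allows up to 0.182 CPM in the library with the least depth (3 counts, counting error only). MKI67, a proliferation marker, had a log2 fold change of -0.40 ± 0.21 (adjusted p = 0.235; -0.25 with 17 libraries), and ENO2, a neuronal enolase, -0.41 ± 0.23 (adjusted p = 0.281). CHGA, a neuroendocrine marker, had 0.16 ± 0.12 CPM in controls and was too low to test.

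Of the gene lists reported here, 3 passed in camera with the preset correlation. The 32 cytosolic ribosomal proteins were higher under propranolol (median log2 fold change 0.45, adjusted p = 3.33e-09), with all 32 above 0, as in RPS28 (0.94 ± 0.27) and RPL18 (1.05 ± 0.34). The 13 mitochondrially encoded subunits of oxidative phosphorylation (median 0.89, adjusted p = 2.51e-04) and the 31 nuclear-encoded ones (median 0.29, adjusted p = 0.022) were higher too. MT-ND1 had a log2 fold change of 1.12 ± 0.40 and COX5A of 0.52 ± 0.14, and neither passed alone. With an estimated correlation the adjusted p was 0.893 for each of these 3 lists. In fry these lists did not pass either (adjusted p = 0.306 for the ribosomal and mitochondrially encoded lists, 0.421 for the nuclear-encoded list). No single member of them passed over all genes tested with 19 libraries, and with 17 libraries 8 ribosomal proteins rose, 5 nuclear-encoded subunits rose and 1 fell. The nuclear-encoded list did not pass without propranolol 2 (adjusted p = 0.0626), without propranolol 5 (0.0561) or with the stromal covariate (0.0948), and without propranolol 2 and combination 4 its median was 0.14 (adjusted p = 0.0443). The stromal covariate was lowest in propranolol 2 (0.422) and combination 4 (0.0369), so it largely marks those 2 libraries. Adjusted over the list alone, 19 of the 32 ribosomal proteins rose, 4 nuclear-encoded subunits rose and 1 fell, and none of the mitochondrially encoded subunits passed (20, 7 and 1, and 0 with 17 libraries). The 28 genes of the hypoxia response (median -0.24, adjusted p = 0.292) did not pass. With each library's trend on gene length and GC content removed, the ribosomal (adjusted p = 2.16e-06), mitochondrially encoded (0.00283) and nuclear-encoded (0.00506) lists still passed in camera. The mitochondrial share of counts averaged 2.28% ± 1.20 (SD, n = 6) under propranolol. Without propranolol 2 and combination 4 the count of genes rose to 2314 (1306 higher, 1008 lower), all 20 genes of the 19-library test among them. The count was 1418 with DESeq2 (1026 higher, 392 lower), 4282 with sample quality weights (2157 higher, 2125 lower) and 5 with library totals (1 higher, 4 lower). It was 1972 without propranolol 6 (1452 higher, 520 lower) and 1532 at an adjusted p under 0.1 (1164 higher, 368 lower). The balance of higher and lower genes thus depended on the setting.

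The comparison of combination with control asked what both blockers together did. Gene lists of translation and metabolism differed in camera with the preset correlation, and with an estimated correlation none of these lists passed (adjusted p = 0.668 for the hypoxia list and 0.515 for each of the other 5). In fry none of them passed either (adjusted p = 0.117 to 0.192). The 32 ribosomal proteins were higher (median log2 fold change 0.34, adjusted p = 1.41e-08). The 13 mitochondrially encoded subunits of oxidative phosphorylation were higher (median 1.21, adjusted p = 8.9e-08), with all 13 above 0, and the 31 nuclear-encoded ones were higher as well (median 0.39, adjusted p = 5.76e-07). The 28 hypoxia response genes (median -0.33, adjusted p = 9.12e-04), the 18 glycolysis genes (median -0.29, adjusted p = 0.00147) and the 25 genes of fatty acid synthesis and lipid storage (median -0.28, adjusted p = 0.00981) were lower. Values behind these lists include -0.63 ± 0.18 for P4HA1, -0.84 ± 0.30 for the lactate exporter SLC16A3, -0.45 ± 0.18 for FASN and -0.39 ± 0.12 for ACSL3. Without propranolol 2 and combination 4 the median was 0.77 for the mitochondrially encoded subunits, 0.18 for the ribosomal proteins and 0.27 for the nuclear-encoded subunits, and all of these lists still passed with the preset correlation. The mitochondrial share of counts averaged 2.49% ± 2.00 (SD, n = 6) in combination libraries, and 1.75% without combination 4, whose share was 6.16%. The fatty acid list did not pass without combination 3 (adjusted p = 0.0514).

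KLK3 had 5338 ± 374 CPM in controls (n = 7) and 5325 ± 1263 CPM under the combination (n = 6), a log2 fold change of 0.00 ± 0.14 (edgeR adjusted p = 0.992). Combination 4 was at 7843 CPM and the other 5 at 4521 to 5247, and with 17 libraries the log2 fold change was -0.15 ± 0.10 (adjusted p = 0.376). FKBP5 had 77.5 ± 11.9 CPM against 116.4 ± 35.3 (-0.59 ± 0.27, adjusted p = 0.311). The 26 components of adrenergic receptor signalling were lower (median -0.21, camera adjusted p = 0.0377), with ADCY1, an adenylyl cyclase, at -0.56 ± 0.13 and ADRA2A at -0.87 ± 0.34. With an estimated correlation the adjusted p of this list was 0.515, and in fry it was 0.138. It did not pass without combination 1 (adjusted p = 0.0533), 2 (0.0618), 3 (0.0514) or 6 (0.0993), and without propranolol 2 and combination 4 its median was -0.11 (adjusted p = 0.026). Adjusted over the list alone, 10 mitochondrially encoded subunits rose and 1 adrenergic component fell, and no member of the other 5 lists passed. With 17 libraries, adjusted over the list alone, these counts were different: no mitochondrially encoded subunit rose, 12 nuclear-encoded subunits rose, and 7 adrenergic components and 3 fatty acid genes fell.

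No single gene passed between combination and control in edgeR's test (smallest adjusted p = 0.28). At an unadjusted p under 0.05 there were 2713 of 17418 genes, and DESeq2 called 33. The protein-coding genes with the smallest p among those higher were FP565260.6 (0.91 ± 0.19), SEMA3B, a secreted semaphorin (0.82 ± 0.18), SAT1, an enzyme of polyamine catabolism (0.49 ± 0.10), and the keratin KRT10 (0.61 ± 0.14). Among those lower they were EXOC4 (-0.57 ± 0.12), PRKX (-0.56 ± 0.12), DDX21 (-0.53 ± 0.12) and TBC1D9 (-0.46 ± 0.10). All 8 had an adjusted p of 0.28. MKI67 (-0.18 ± 0.21, adjusted p = 0.678), ENO2 (-0.35 ± 0.23, adjusted p = 0.446) and ADRB1 (-0.38 ± 0.60, adjusted p = 0.767; -0.12 with 17 libraries) did not pass either. Without the 2 libraries of few genes the count stayed at 0, with 4042 genes at an unadjusted p under 0.05, and with sample quality weights it was 3998. It was 31 with those 2 libraries left out and the length and GC trend removed, and 1037 with propranolol 2, propranolol 5 and combination 4 left out, where all 8 genes named above passed (adjusted p = 0.0237 to 0.0303). With each library's trend on gene length and GC content removed, the fatty acid (adjusted p = 0.126) and adrenergic (0.265) lists did not pass in camera, while the hypoxia (0.00412), glycolysis (0.0197), ribosomal (5.7e-06), mitochondrially encoded (1.03e-04) and nuclear-encoded (2.49e-05) lists did. With the 2 libraries left out as well, the fatty acid list passed (0.00808) and the adrenergic list did not (0.244).

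**Figure D3:**
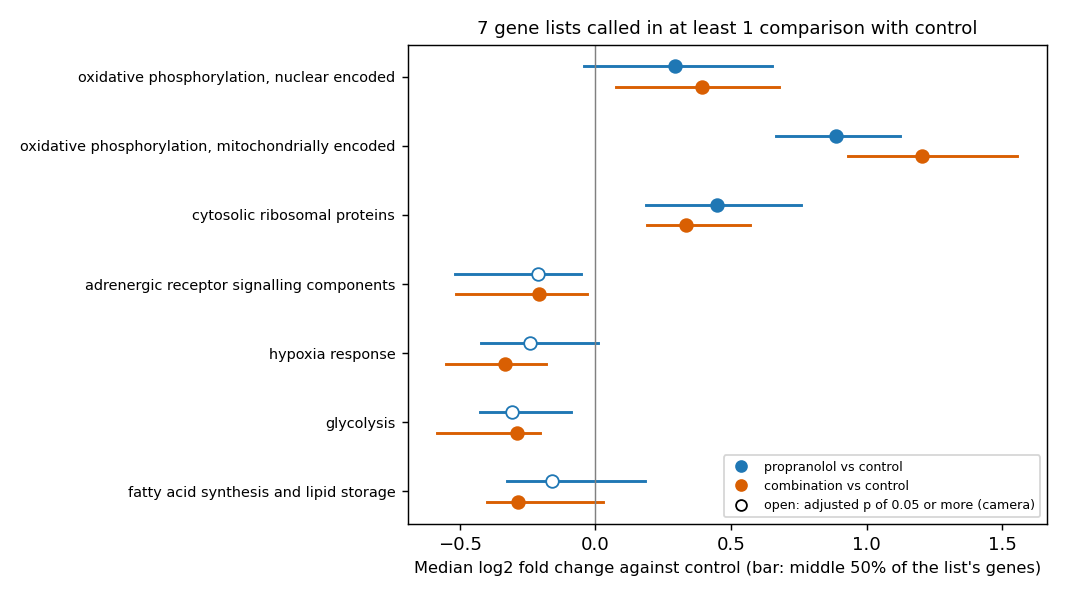
Median log2 fold change against control of 7 gene lists that passed in at least 1 comparison with control, for propranolol and for combination, with bars over the middle 50% of each list's genes; filled points passed in camera with the preset correlation. The mitochondrially encoded subunits have medians of 0.89 and 1.21, and the hypoxia response genes of -0.24 and -0.33.

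The comparison of combination with propranolol tested the difference between the treated groups, which differ by SR59230A. VHL was at 192 ± 13.2 CPM under the combination (n = 6) against 75.9 ± 27.6 CPM under propranolol (n = 6), a log2 difference of 1.34 ± 0.19 (edgeR adjusted p = 0.00799). B3GNT10 was at 22.3 ± 5.28 against 7.88 ± 2.69 CPM (1.499 ± 0.199, adjusted p = 0.00571), and ZNF587, a zinc finger gene, at 35.3 ± 5.15 against 22.8 ± 2.02 CPM (0.63 ± 0.10, adjusted p = 0.0263). EIF5B was lower under the combination, at 88.4 ± 27.7 against 193 ± 42 CPM (-1.13 ± 0.18, adjusted p = 0.0251). The EIF5B call was lost without any 1 of propranolol 3 or 5 or combination 1, 2, 3, 5 or 6 (adjusted p = 0.0596 to 0.0937), and the ZNF587 call without any 1 of propranolol 1, 3 or 5 or combination 2, 3, 5 or 6 (0.0598 to 0.0937). The fifth gene that passed was the pseudogene AC005912.1 (0.72 ± 0.13, adjusted p = 0.0498), whose reads may be shared with copies and which is named because so few genes passed. The mice of the combination group had received propranolol too, yet the combination means of VHL, B3GNT10, ZNF587 and EIF5B lay nearer to the controls (171 ± 13.8, 19.2 ± 1.19, 31.2 ± 1.73 and 89.3 ± 14.9 CPM) than to propranolol. Of the 25-mers of ZNF587 9.2% occur in more than 10 genes, of VHL 6.8%, and of EIF5B and B3GNT10 0%.

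These 5 genes were the only ones of 17418 to pass in that test, 4 higher and 1 lower, and no gene list passed (smallest adjusted p = 0.0804, fatty acid synthesis and lipid storage). KLK3 (-0.20 ± 0.14, and -0.28 with 17 libraries), FKBP5 (-0.13 ± 0.27), MKI67 (0.22 ± 0.21, and 0.03 with 17 libraries), ENO2 (0.06 ± 0.24) and ADRB1 (-1.17 ± 0.63) did not pass. The ADRB1 value leans on propranolol 3, at 11.7 CPM. Without propranolol 2 and combination 4, 60 genes passed (43 higher, 17 lower), and the ribosomal protein list (median -0.19, adjusted p = 8.71e-04) and the fatty acid list (median -0.14, adjusted p = 0.0178) were lower under the combination, with an adjusted p of 0.834 for both with an estimated correlation. With only the 2 groups in the fit no gene passed, and at an unadjusted p under 0.05 there were 506.

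Neuronal, immune and host-tissue lists were tested in both comparisons with control because the series title names nerves and immunity. Only 6 members of the neuroendocrine list were expressed enough to test (median log2 fold change 0.94 for propranolol, camera adjusted p = 0.244, and 0.30 for combination, adjusted p = 0.722), and with 17 libraries its propranolol median was 0.55. Adjusted over the list alone, 3 of its 6 tested members and 5 of the 22 tested MHC class I genes rose under propranolol, and none of them passed over all genes with 19 libraries. With 17 libraries 2 neuroendocrine members, 2 MHC class I genes, 5 interferon genes and 3 neurotrophin and axon guidance genes rose over all genes tested, and 1 nerve and Schwann cell gene fell. The nerve and Schwann cell list, with 5 tested genes, had medians of -0.38 (adjusted p = 0.295) and -0.22 (0.278), and adjusted over the list alone 3 of the 5 fell under propranolol. With 17 libraries and 7 tested genes its propranolol median was -0.33 (camera adjusted p = 0.306, fry adjusted p = 0.033). The neurotrophin and axon guidance list gave medians of -0.10 (adjusted p = 0.812) and -0.19 (0.334). Type I interferon genes (-0.08, adjusted p = 0.718, and 0.13, 0.782), MHC class I genes (0.30, 0.159, and 0.13, 0.216) and secreted chemokines and cytokines (0.09, 0.871, and -0.15, 0.262) did not pass. With 17 libraries the chemokine medians were 0.32 and 0.03, and the interferon medians 0.06 and 0.05. Nor did the cell cycle lists, with medians of 0.04 and 0.11 in S phase and -0.09 and 0.05 in G2 and mitosis (0.00 and -0.06 with 17 libraries). The camera direction for the G2 and mitosis list and for the type I interferon list under propranolol was up, opposite in sign to their medians. Markers of fibroblasts and matrix had medians of -0.26 (adjusted p = 0.232) and -0.21 (0.262), and with the trend on gene length and GC content removed the list was lower under propranolol (adjusted p = 0.0295) and did not pass under the combination (0.126). The propranolol call was lost when propranolol 2 and combination 4 were left out too (adjusted p = 0.208), and without them and with the trend kept the median was -0.13. The myeloid and lymphocyte lists had fewer than 5 tested genes each. The count table lists human genes, so transcripts of the mouse host have no genes of their own in it.

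Taking the mean of both treatments against control, POMK was the only gene that passed in edgeR (-1.54 ± 0.21, adjusted p = 0.00662), with 4542 genes at an unadjusted p under 0.05. Without propranolol 2 and combination 4 it was 2423 genes (1157 higher, 1266 lower), and with DESeq2 1569. The fold changes of the treatments against control correlated across genes (Pearson r = 0.701, covariance 0.226). These comparisons share the 7 controls. Simulated unchanged groups that shared simulated controls gave a median r of 0.461 (highest of 50 simulations 0.482) and a covariance of 0.063. The simulated genes were drawn independently, without the trends on gene length that the libraries carry. Each gene had 1 spread, estimated over all 19 libraries, propranolol 2 and combination 4 included. The simulated covariance of 0.063 exceeds the 0.0177 that the variance between the real controls gives for shared controls. With 17 libraries these values were 0.0229 and 0.0199. The simulated r of 0.461 is thus not a matched baseline for 19 libraries. The gap between 0.461 and 0.701 therefore does not measure a shared response to treatment. With the controls split into sets of 3 and 4 the median r was 0.619, with a range of 0.536 to 0.66 over 70 splits. No called gene was shared, since the combination had none. Without the 2 libraries of few genes r was 0.648 (0.417 simulated, 0.45 with split controls) and the covariance 0.088 (0.023 simulated).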

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

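Chosen only after the result was seen were the tests of low library complexity (for both patterns), of an opposite strand setting, of gene length and GC content for the genes that set propranolol apart, of RNA quality for the length trend, and every value without propranolol 2 and combination 4. The repeated-sequence test was written after the gene names, but before any sequence value, had been seen.

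Combination 4 and propranolol 2 lay far from the rest of their groups in many measures. Combination 4 was far from the other 5 in genes detected (13854), genes at 1 to 10 counts (385), mitochondrial tRNA share (1.3%), share of the 50 most abundant genes (24.6%), length slope (-0.433) and mean log2 CPM of stromal markers (0.0369). It was also far from them in CPM of KLK3 (7843), EIF5B (144), BRI3 (274), B3GNT10 (32.8), KRT10 (133), DDX21 (94.8) and ZNF587 (45.3). Propranolol 2 was far from its group in genes detected (15334), genes at 1 to 10 counts (533), mitochondrial share (4.6%), mitochondrial tRNA share (2.18%) and stromal markers (0.422). These 2 libraries account for 18 of the 29 values found.

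Single libraries elsewhere made up the other 11. Propranolol 3 had the largest total (60.3 M counts against 23.9 to 35.8 M) and an ADRB1 level of 11.7 CPM, where the other propranolol libraries had 1.09 to 4.72. Control 2 was far from the other controls in FKBP5 (189 CPM), PRKX (34 CPM) and the share of counts in antisense genes (0.467%), and control 5 in TBC1D9 (36.5 CPM), CHGA (0.404 CPM) and mitochondrial tRNA (0.0578%). Combination 3 was far from its group in CHGA (0.337 CPM), combination 5 in the antisense share (0.529%) and propranolol 6 in TBC1D9 (42.4 CPM). Chance alone marks about 1 in 20 groups this way, and here it was 29 of 105 (27.6%).

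VHL (1.34), B3GNT10 (1.5), ZNF587 (0.63), EIF5B (-1.13) and the pseudogene AC005912.1 (0.72) differed between the treated groups in a direct test, in log2 units of combination over propranolol. Chance could not be excluded for this count of 5: of 100 splits of the libraries, the real one included, 7 gave as many, and the highest other gave 2237. Without the 2 libraries of few genes, 2 of 100 splits were as large, with a real count of 60 and a highest other of 637. For propranolol against control, 2 of 100 splits were as large with 19 libraries (real count 20, highest other 2606). With 17 libraries 3 of 100 were (real count 2314, highest other 3809). The split with 2606 genes exchanged control 5, the control with the lowest length slope, for propranolol 6, the propranolol library with the highest. Apart from that exchange the split keeps the treatment groups, and leaving out propranolol 6 alone gave 1972 genes. A structure of the samples other than treatment may be involved, but this split cannot separate it from treatment. The split with 637 genes, the highest of those drawn, mixed the treated groups. On 1 side were propranolol 1 and 6 and combination 2, 3 and 5, with length slopes of -0.11 to -0.00274. On the other were propranolol 3, 4 and 5 and combination 1 and 6, at -0.354 to -0.136. Among these libraries, a structure other than the difference between treatments thus went with more genes than the real split (60). For combination against control, where edgeR called 0 genes (2713 at an unadjusted p under 0.05, 33 in DESeq2), a real count of 0 leaves nothing for splits to test, since all 100 splits give at least 0. For both treatments against control chance was not excluded with 19 libraries (5 of 100, real count 1, highest other 1840). With 17 libraries 2 of 100 splits were as large (real count 2423, highest other 4307). Shares of 2 or 3 of 100, unadjusted for the comparisons tested, make chance less likely but do not exclude it. Those with 17 libraries also rest on libraries left out after the data had been examined.

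The first pattern is a set of 52 genes, VHL and EIF5B among them, that were lower (38) or higher (14) in propranolol than in both other groups with 17 libraries. For the 5 genes that passed with 19 libraries, low complexity of single libraries is argued against, since all 5 still passed in the same direction without propranolol 2 and combination 4. The set of 52 was defined without those libraries, so no such test was made of it. An opposite strand setting is argued against if the libraries were directional, since the antisense share of propranolol was 1.02 times that of controls. In non-directional libraries the setting would leave that share unchanged, so the ratio cannot tell. Counting with strand in 1 group and without it in another was not tested. How many of the 52 genes stay called once the trend on gene length and GC content is removed was not counted. Of the 2314 genes called for propranolol against control with 17 libraries, 42.2% were still called without that trend. For the 60 genes called between combination and propranolol with 17 libraries, length and GC content as the whole cause are argued against. Of these 60 genes, 78.3% were still called with the trend removed. With 19 libraries only VHL of the 5 genes was (1.34 ± 0.19 before, 1.47 ± 0.19 after), because errors grew while folds stayed, as for EIF5B (-1.13 ± 0.18 and -1.08 ± 0.34), B3GNT10 (1.499 ± 0.199 and 1.646 ± 0.313), ZNF587 (0.63 ± 0.10 and 0.71 ± 0.25) and AC005912.1 (0.72 ± 0.13 and 0.72 ± 0.24). Repeated sequence stays open: the 38 lower genes have a median of 6.076% of 25-mers found in more than 10 genes (10000 random lists: median 0.474%, upper end of the middle 95% 1.685%; the 14 higher genes 0.888%). By 25-mers shared with any other gene, the lower genes have a median of 19.269% (random 6.72%) and the higher genes 50.377% (random 6.089%). The random lists were matched on expression, not on biotype or gene length, and both sets hold pseudogenes and non-coding genes. The excess therefore need not reflect counting. A difference in how multiply aligned reads were counted may contribute, as may an effect of propranolol that SR59230A undoes, which was not tested.

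The second pattern is the dependence of fold changes against control on gene length. Low complexity of 2 libraries is argued against as its cause, since without them the rank correlation of fold change with length for the mean of both treatments was -0.448. RNA quality or library chemistry that varies between tumours stays open: 4 of 7 control libraries lay inside the range of slopes of the 10 treated libraries (-0.354 to -0.00274), so the slope also varied among untreated tumours. That count rests on propranolol 6 (-0.00274): without it the range ends at -0.0689 (combination 5) and 1 control, control 5 (-0.16), lies inside. A treatment effect on transcripts by length was not tested and stays open too.

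The third pattern is the rise in genes called against control once the 2 libraries were left out. Of the 2423 genes called for the mean of both treatments against control, 49.7% were still called with the trend on gene length and GC content removed. That is just under the 50% set beforehand, and for propranolol against control it was 42.2% of 2314. A call can be lost because its error grows, and folds before and after were not compared for these genes. The lost calls therefore do not show that the trend caused them, and both the trend and an effect of treatment stay open.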

How the results depend on the processing

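Chosen after the data had been examined were the values without propranolol 2 and combination 4, those that also left out propranolol 5, and those with the length and GC trend removed; the other alternatives were planned. Counts are given in the order propranolol against control (20 genes), combination against control (0; 2713 at an unadjusted p under 0.05), combination against propranolol (5) and both treatments against control (1). DESeq2 called 1418, 33, 58 and 1569, and voom with quality weights 4282, 3998, 596 and 5469. With a covariate of stromal markers the counts were 709, 0, 47 and 72, with log2(FPKM + 1) 34, 0, 10 and 6, and at an adjusted p under 0.1 1532, 0, 16 and 2. The stromal score was 0.422 in propranolol 2 and 0.0369 in combination 4, against 1.33 to 1.77 in the other 17 libraries. That covariate therefore largely marks those 2 libraries, and its counts do not isolate stromal content. Library totals gave 5 for propranolol. Between combination and propranolol, log2(FPKM + 0.1) gave 11, no low count filter 3, and a fit of only the 2 groups 0 (506 at an unadjusted p under 0.05). RLE factors left all 4 counts as they were.

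Without propranolol 2 and combination 4 the counts were 2314, 0, 60 and 2423, with propranolol 5 left out too 233, 1037, 50 and 1970, with the trend removed 9, 0, 1 and 0, and with both the 2 libraries out and the trend removed 1229, 31, 69 and 1501. The cause was not tested for the differences between tools. Scaling by library totals moved the median log2 fold change of propranolol from -0.03 to -0.20.

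Leaving out 1 library at a time gave 11 to 1972 genes for propranolol against control: 12 without control 1, 13 without control 2, 11 without control 4, 12 without control 7, 35 without propranolol 1, 11 without propranolol 3, 12 without propranolol 5 and 1972 without propranolol 6. Combination against control stayed at 0 in edgeR each time. Combination against propranolol gave 2 to 15: 12 without propranolol 2, 2 without propranolol 3 or 5, 3 without combination 1 or 5, 2 without combination 2, 3 or 6, and 15 without combination 4. The mean of both treatments against control gave 1 to 3, with 3 without combination 4 or combination 5. The causes were not tested.

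With the replicate number as a block the counts were 2, 0, 1 and 0. The numbers were taken not to pair the animals. Of 18 correlations between same-numbered libraries 5 exceeded 0.1 (range -0.424 to 0.303, median 0.016). Differently numbered libraries were not set beside them, so these values do not settle whether animals were paired. The first principal component held 75.3% with a larger set of variable genes, 88.3% with library totals and 28.2% without the 2 libraries of few genes, against 86.5%.

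Of the named genes' values, 510 kept their side of the threshold without single libraries, 24 lost and 1 gained a call. Under the other alternatives 609 kept it, 35 lost and 28 gained a call. For lists, 258 kept and 31 lost a call without single libraries, and 896 kept, 53 lost and 11 gained it otherwise. No call was reversed; a sign change of a gene or list called under neither setting is not counted as reversed.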

Other observations

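The values without propranolol 2 and combination 4 were chosen after the data had been examined. In them the ribosomal protein genes, whose products build the translating ribosome, include 8 that rose under propranolol over all genes tested, among them RPS28 (log2 fold change 0.63, edgeR adjusted p = 0.0196) and RPL18 (0.56, adjusted p = 0.0325). ZBTB16, a zinc finger gene, fell (-0.72, adjusted p = 0.018), as did SI, sucrase-isomaltase (-1.10, adjusted p = 0.0218) and ADCY1 (-0.48, adjusted p = 0.0272). COX5A, a subunit of cytochrome c oxidase, rose (0.46, adjusted p = 0.0291). Under the combination none of these passed in edgeR (RPS28 0.32, ZBTB16 -0.68, ADCY1 -0.57), where no gene did and 4042 had an unadjusted p under 0.05.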
